A study of Mus musculus with 8 samples.

How the data were processed

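RNA had been isolated with a column kit from dendritic cells grown from the marrow of mice 8-10 weeks old, made into libraries with the SMARTer Ultra Low Input and Nextera kits, and sequenced as single-end reads of 75 bases, per the labels. The authors deposited 1 table of expected counts, with 25624 mouse genes under Ensembl identifiers and 92 spike-in controls in 8 libraries. The submitters' notes name STAR and DESeq2 without a version or role, and give no counting program, genome build or annotation release. Values were mostly whole numbers, with 10.4% to 11.4% of them fractional in a library, they were not scaled between libraries, and rounding for the tests changed 3902 genes. The spike-in controls were left out of the tests.

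The libraries were grouped by their labels into unstimulated, yeast, yeast with cytochalasin D and hyphae, 2 each, before the data were examined. The 6 comparisons, the tests, the gene lists, the rule for naming genes and the alternatives listed first were also chosen before the data were examined. The labels do not say whether the libraries of a group came from separate cultures or mice, so p-values measure only the spread between these libraries. Replicate numbers were not used as pairs.

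Total counts ran from 30350530 to 49471974, and 15615 to 16442 genes had a count in a library. After scaling, 1 CPM stood for 28 counts in yeast replicate 1 and for 48 in unstimulated replicate 2. A group with 0 counts was given a floor of 3 counts over the group, from which a fold is a lower bound, and with 1 to 3 counts a fold has its 95% interval, from the exact binomial interval of the share of counts. Such intervals and floors cover counting error only.

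Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13435, and libraries were scaled by TMM factors from 0.9205 to 1.165. A quasi-likelihood negative binomial model with 1 mean per group and 4 residual degrees of freedom was fitted to all 8 libraries, and each comparison was a contrast in it. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Standard errors are Wald errors from the fitted information, scaled by the quasi-dispersion.

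Gene lists held 43 pathways, marker sets of other cell types and signs of RNA quality, of which 41 had at least 3 tested members. Each was tested by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and by fry, which asks whether a list moves on balance one way without comparing it with other genes. Members were counted as rising or falling after adjustment over all genes and again after adjustment over the list alone. Some genes stood in more than 1 list.

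Genes were named by rule. In each comparison these were the 10 largest rises and 10 largest falls among called genes with both libraries of one group above both of the other and at least 5 CPM in the higher group, gene models without an established name being passed over. To them were added at most 4 members of each list by smallest p, 24 cytokine, receptor and signalling genes fixed beforehand, and the 10 genes with the smallest p of the direct difference among those called in opposite directions in 2 comparisons against unstimulated cells.

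Alternatives fixed in advance were the legacy quasi-likelihood fit, no filter on low counts, a filter at a mean of 5 CPM, RLE scaling, library size alone, each library left out in turn, a fit of the groups compared alone, a replicate block, DESeq2 1.42.0 and limma-voom. A fit that left out 1 library assumed that the lone library of that group varied like the other groups. Chosen after the data were seen were a smooth curve in transcript length and GC content (spline with 4 degrees of freedom) subtracted within each library, thinning every library to the smallest total, leaving out the mitochondrially encoded genes, and counts of list members, of genes called in opposite directions and of genes shared by 2 stimuli against unstimulated cells, without single libraries. Lengths and GC content were matched to 99.8% of the genes tested. The curve was subtracted with its intercept, so it also rescaled each library. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

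Steps were tested on simulated, independent genes with the spread of each pooled over libraries, 200 of 13435 changed. Of 50 genes changed 1.5-fold 4% were recovered, at 2-fold 44%, 4-fold 88% and 8-fold 96%. Of 124 calls 8 were false, and a comparison without change gave 0 calls by edgeR. A list of 25 members shifted 2-fold was called (adjusted p = 2.6e-42, or 0.004 with an estimated correlation) and 0 others. Correlated genes were not tested.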

Results

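Messenger RNA was measured by single-end sequencing in dendritic cells grown from mouse bone marrow, sentinel cells that take up microbes and instruct T cells. The cells were left unstimulated, given the yeast form of the fungus C. albicans, given yeast together with cytochalasin D, or given hyphae. Cytochalasin D inhibits actin polymerisation and so blocks the uptake of particles, and hyphae are the long filaments of the fungus, which can exceed the size a cell can engulf. Uptake itself was not measured. Each of the 4 groups had 2 libraries. Total counts were 38435582 and 41197891 in the unstimulated libraries and 30350530 and 39996386 with yeast. They were 37320401 and 40473452 with yeast and cytochalasin D, and 49471974 and 41637144 with hyphae. No library held cells given cytochalasin D without yeast, so any effect of the drug itself and of blocked uptake were measured together. The labels state neither the dose of fungus nor the time of stimulation.

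The first principal component of log2 CPM (counts scaled by effective library size) held 65.8% of the variance and ran from unstimulated cells (-94.8 and -96.3) through yeast (-26.1 and -17.9) and hyphae (27.8 and 31.3) to yeast with cytochalasin D (87.5 and 88.4). Yeast replicate 1 stood apart from its partner, at -68.3 against -21 on the second component (16.9% of the variance). Mitochondrially encoded genes took 11.1% of the counts in yeast replicate 1 and 5.02% in yeast replicate 2, against 4.95% and 5.92% in unstimulated cells, 4.16% and 3.99% with yeast and cytochalasin D, and 3.77% and 3.72% with hyphae. Over 4757 genes above 32 CPM, the log2 difference between the yeast libraries had an SD of 0.581, against 0.143, 0.0682 and 0.071 in the unstimulated, cytochalasin D and hyphae pairs.

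**Figure D1:**
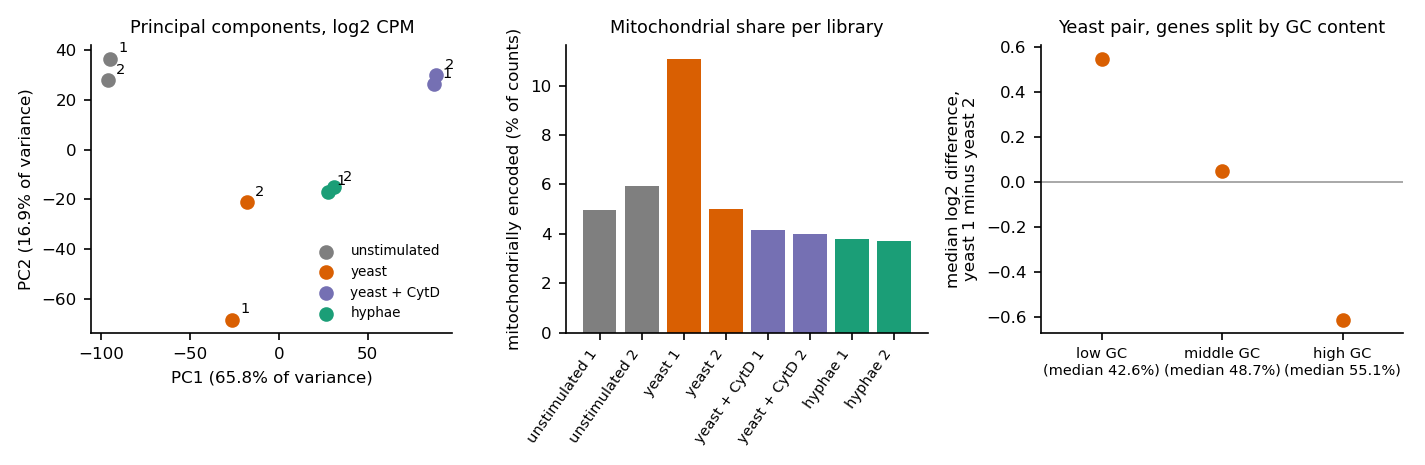
The 8 libraries by the first and second principal component of log2 CPM, the percent of counts from mitochondrially encoded genes in each library (bars from 0), and the median log2 difference between yeast replicates 1 and 2 in genes of low, middle and high GC content. The yeast libraries lie farther apart than the other pairs, and the median difference runs from 0.55 in genes of low GC content to -0.61 in genes of high GC content.

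Hyphae were compared with yeast to ask how the physical form of the fungus changed the response of the cells. Several cytokine transcripts were higher with hyphae. Csf3, the granulocyte growth factor, rose by 5.72 ± 0.19 (log2 fold change ± standard error, as for all genes named here, with 2 libraries per group), Csf2, the growth factor for granulocytes and macrophages, by 4.43 ± 0.30, and Tnf, a central inflammatory cytokine, by 2.79 ± 0.13, from a mean of 122 to 841 CPM. Il10, which dampens inflammation, rose by 5 ± 0.42. Of the cytokines that promote Th17 cells, Il6 rose by 3.16 ± 0.23, Il23a, a subunit of IL-23, by 2.20 ± 0.22, Il12b, the subunit shared by IL-12 and IL-23, by 1.49 ± 0.13 and Il1b by 0.95 ± 0.10. Cxcl10, a chemokine for activated T cells, rose by 4.08 ± 0.19 and Il27, which acts on Th1 cells, by 3.24 ± 0.26, while the IL-12 subunit Il12a did not pass (-0.05 ± 0.26, adjusted p = 0.89). Of type I interferon-stimulated genes, the antiviral genes Rsad2 and Cmpk2 rose by 2.65 ± 0.14 and 2.61 ± 0.11. Of the Th17-promoting cytokines, 6 of 8 rose and 2 did not pass. Adjusted over the list alone, 8 rose (camera adjusted p = 1e-05, or 0.144 with an estimated correlation). For Th1-promoting cytokines and chemokines, 7 of 10 rose (4 without 1 hyphae library to 9 without yeast replicate 1) and 3 did not pass. 8 rose adjusted over the list alone (camera adjusted p = 1e-05, or 0.144 if estimated). Among other inflammatory and regulatory cytokines, 14 of 16 rose (8 without hyphae replicate 2 to 16 without yeast replicate 1) and 2 did not pass. 16 rose adjusted over the list alone (camera adjusted p = 1.8e-12, or 0.0542 if estimated). Of the interferon-stimulated genes, 23 of 26 rose (14 without 1 hyphae library to 26 without yeast replicate 1) and 3 did not pass. 25 rose adjusted over the list alone (camera adjusted p = 2e-15, or 0.144 if estimated). Il23a had an adjusted p of 0.0543 with these groups alone (5.35e-08 to 0.0543 over alternatives) and Il1b 0.0988 with these groups alone (5.05e-17 to 0.0988).

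Several dendritic cell maturation and costimulation genes also rose with hyphae, with the costimulatory receptor Cd40 at 2.13 ± 0.19 and the maturation marker Cd83 at 1.64 ± 0.09. Several NF-kB targets and immediate-early genes rose as well, with the NF-kB regulator Nfkbiz at 2.18 ± 0.13 and Egr1 at 2.03 ± 0.16, whereas Nfkb2, which encodes the precursor of p52, and Egr2 did not pass (1.05 ± 0.30, adjusted p = 0.062 and 0.28 ± 0.12, adjusted p = 0.15). Dusp10, a phosphatase that limits MAP kinase signalling, rose by 2.70 ± 0.12. The oxygen-sensing hydroxylase Egln3 and the angiogenic factor Vegfa, both HIF-1 targets, rose by 3.40 ± 0.12 and 2.66 ± 0.10, and Nos2, the inducible nitric oxide synthase, and Arg1, arginase 1, by 2.78 ± 0.17 and 2.51 ± 0.23. Among maturation genes, 10 of 18 rose (5 without 1 hyphae library to 12 without 1 yeast library), 1 fell (0 without 1 library of unstimulated, cytochalasin D or hyphae to 2 without yeast replicate 1) and 7 did not pass, and the same over the list alone (camera adjusted p = 0.00016, or 0.144 with an estimated correlation). For NF-kB subunits and feedback targets, 9 of 18 rose (3 without 1 hyphae library to 16 without yeast replicate 1) and 9 did not pass. 14 rose adjusted over the list alone (camera adjusted p = 3.1e-06, or 0.22 if estimated). Of the AP-1, EGR and NR4A immediate-early genes, 10 of 22 rose (3 without hyphae replicate 1 to 17 without 1 yeast library), 1 fell (0 without 1 library of unstimulated, cytochalasin D or hyphae to 2 without yeast replicate 2) and 11 did not pass. 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.2e-06, or 0.293 if estimated). Of the MAP kinase phosphatases and SOCS genes, 7 of 16 rose (3 without 1 hyphae library to 12 without yeast replicate 2), 1 fell (0 without 1 library of unstimulated, cytochalasin D or hyphae to 2 without yeast replicate 2) and 8 did not pass. 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00012, or 0.144 if estimated). Among glycolysis genes and HIF-1 targets, 17 of 26 rose (6 without 1 hyphae library to 26 without yeast replicate 2) and 9 did not pass. 23 rose adjusted over the list alone (camera adjusted p = 3.4e-11, or 0.163 if estimated). In nitric oxide, arginine and itaconate metabolism, 5 of 9 rose (2 without 1 hyphae library to 7 without yeast replicate 2) and 4 did not pass, and the same over the list alone (camera adjusted p = 0.0043, or 0.144 if estimated). Actin cytoskeleton and SRF-MRTF targets gave the calponin Cnn3 at 1.39 ± 0.13, and 4 of 26 rose (2 without 1 library of cytochalasin D or hyphae to 19 without yeast replicate 2) and 22 did not pass. Adjusted over the list alone, 8 rose (camera adjusted p = 0.0015, or 0.429 if estimated). Nfkb2 had an adjusted p of 0.0054 by DESeq2, 0.00014 without yeast replicate 1 (at 0.62), 4.95e-08 without yeast replicate 2 (at 1.64) and 0.00182 with the length and GC curve (at 0.48) (4.95e-08 to 0.258 over alternatives), Egr2 0.000586 without yeast replicate 2 (0.000586 to 0.432) and Cnn3 0.0546 with these groups alone (1.52e-16 to 0.0546).

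Several cell-cycle genes were lower with hyphae, with Rrm2, a subunit of the reductase that makes DNA precursors, at -1.17 ± 0.13 and the DNA topoisomerase Top2a at -1.50 ± 0.23, and 11 of 22 fell (0 without hyphae replicate 2 to 20 without yeast replicate 1) and 11 did not pass. 18 fell adjusted over the list alone (camera adjusted p = 3.8e-09, or 0.144 with an estimated correlation). For cholesterol synthesis and uptake, 4 of 19 fell (0 without 1 hyphae library to 12 without yeast replicate 1) and 15 did not pass. 6 fell adjusted over the list alone (camera adjusted p = 0.017, or 0.163 if estimated). C-type lectin receptors recognise fungal sugars. Clec4n, which encodes Dectin-2, fell by 0.76 ± 0.11, while Clec7a, which encodes Dectin-1, the receptor for beta-glucan, did not pass (-0.69 ± 0.26, adjusted p = 0.11, and -0.21 without yeast replicate 1), at a mean of 2830 CPM with hyphae and 4560 CPM with yeast. Over all C-type lectin receptors and their signalling genes, 2 of 19 fell (0 without 1 hyphae library to 6 without yeast replicate 2) and 17 did not pass, and the same over the list alone (camera adjusted p = 0.96), with a median of 0.12, a mean of -0.04 and a test direction of down. Among mitochondrially encoded genes, 0 of 13 fell (0 without 1 library of unstimulated, cytochalasin D or hyphae to 13 without 1 yeast library) and 13 did not pass. 13 fell adjusted over the list alone (camera adjusted p = 0.00023, or 0.46 if estimated). Their median was -1.28 (-0.41 without yeast replicate 1 and -0.57 with the length and GC curve subtracted), and yeast replicate 1 was the library in which their share was high. Cholesterol genes had an adjusted p of 0.185 without yeast replicate 2 (0.000209 to 0.185 over alternatives), Rrm2 0.0907 with these groups alone and 0.0538 without hyphae replicate 2 (1.5e-09 to 0.0907) and Top2a 0.112 with these groups alone, 0.0861 without hyphae replicate 1 and 0.108 without hyphae replicate 2 (1.12e-08 to 0.112). Clec4n had an adjusted p of 0.166 with these groups alone, 0.0791 without hyphae replicate 1 and 0.114 without hyphae replicate 2 (1.94e-08 to 0.166 over alternatives) and Clec7a 0.0425 by DESeq2, 2.44e-07 without yeast replicate 2 (at -1.08) and 0.0441 with the length and GC curve (at -0.25) (2.44e-07 to 0.371).

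Of 13435 genes tested, 1940 differed between hyphae and yeast by the edgeR test, 1146 higher and 794 lower with hyphae, and 964 of them by at least 2-fold. Camera called 16 of 41 lists, 13 higher and 3 lower, and 0 with an estimated correlation, where 12 lists had an unadjusted p under 0.05 and fry called 26. All genes called in the 6 comparisons had both libraries of one group above both of the other, which chance gives in 33.3% of genes. Scaling by library size alone gave 1035 higher and 1085 lower, and a smooth curve in transcript length and GC content subtracted from each library gave 2023 higher and 3006 lower. The curve also rescaled the libraries, with a median of all genes of -0.0749. The number of genes was 4545 without yeast replicate 1 and 9262 without yeast replicate 2. Leaving out other libraries gave 825 (633 higher, 192 lower) and 828 (635, 193) without unstimulated replicates 1 and 2, 777 (594, 183) and 780 (595, 185) without cytochalasin D replicates 1 and 2, and 335 (311, 24) and 324 (311, 13) without hyphae replicates 1 and 2. It was 171 (169, 2) in a fit of these groups alone and 3110 (1587, 1523) by DESeq2.

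**Figure D2:**
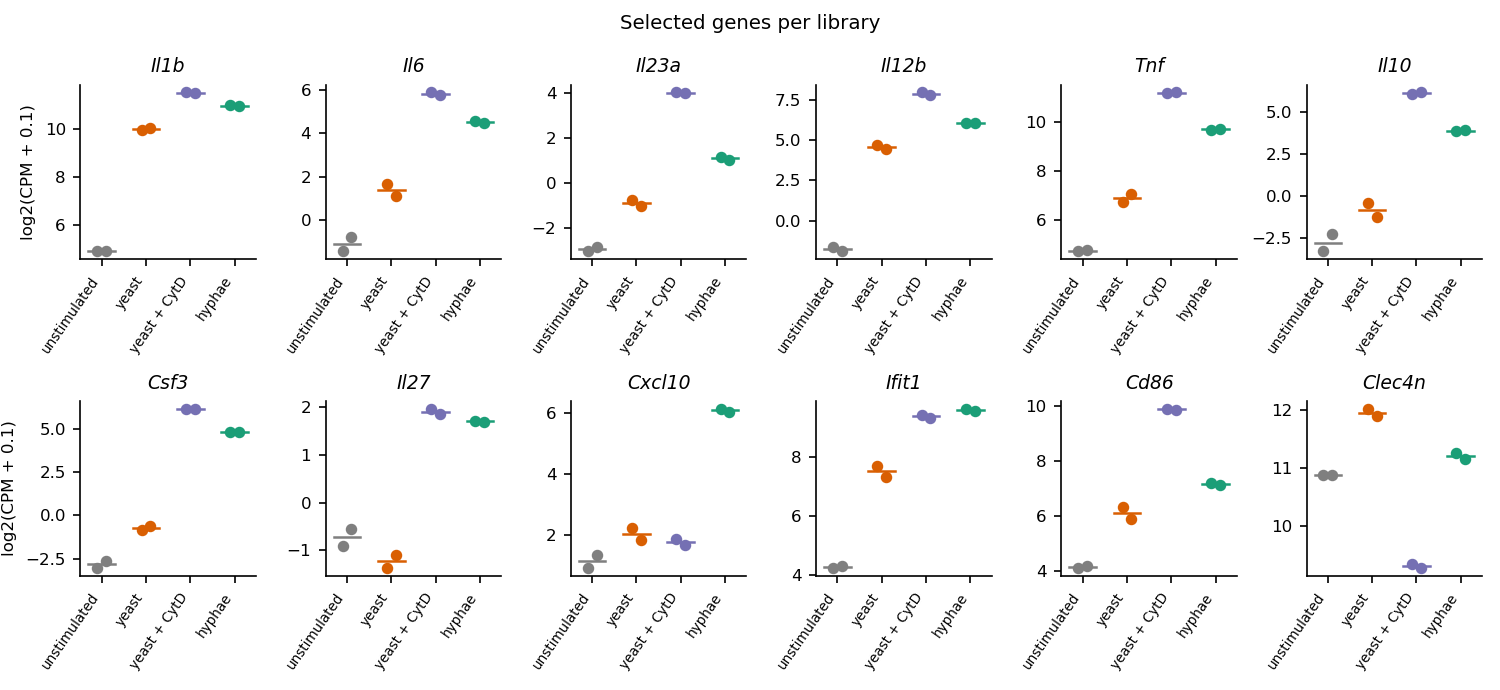
Log2 (CPM + 0.1) of 12 genes in each library (points) with the mean of each group (bars). Tnf averaged 122 CPM with yeast, 841 with hyphae and 2380 with yeast and cytochalasin D.

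Yeast with cytochalasin D was compared with yeast alone to ask how the response changed with an inhibitor of uptake. Several cytokine transcripts rose: Tnf by 4.29 ± 0.13, to a mean of 2380 CPM, Csf3 by 7.06 ± 0.19, Csf2 by 7.04 ± 0.30 and Il10 by 7.24 ± 0.42. Of Th17-promoting cytokines, Il23a rose by 5.16 ± 0.21, Il6 by 4.45 ± 0.23, Il12b by 3.31 ± 0.13 and Il1b by 1.49 ± 0.10. Il27 rose by 3.45 ± 0.26, while Cxcl10 (-0.26 ± 0.21, adjusted p = 0.35) and Il12a (-0.87 ± 0.29, adjusted p = 0.058) did not pass. Cxcl3, a chemokine for neutrophils, fell by 2.78 ± 0.15. Ifit1 and Rsad2, both interferon-stimulated, rose by 1.86 ± 0.14 and 1.35 ± 0.14. Among other inflammatory and regulatory cytokines, 16 of 16 rose, and the same over the list alone (camera adjusted p = 1e-12, or 0.0499 with an estimated correlation). No other call in the 6 comparisons held with an estimated correlation. Of the Th17-promoting cytokines, 7 of 8 rose and 1 did not pass. 8 rose adjusted over the list alone (camera adjusted p = 1.2e-05, or 0.155 if estimated). For Th1-promoting cytokines and chemokines, 4 of 10 rose (2 without cytochalasin D replicate 1 to 4 without 1 library of unstimulated, yeast or hyphae) and 6 did not pass. 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.3), with a median of -0.03 and a mean of 0.78. Of the neutrophil-attracting CXC chemokines, 3 of 6 rose, 2 fell and 1 did not pass, and the same over the list alone (camera adjusted p = 0.54). Of the interferon-stimulated genes, 16 of 26 rose, 4 fell (1 without cytochalasin D replicate 2 to 4 without 1 yeast library) and 6 did not pass. 18 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.00059, or 0.246 if estimated). Cxcl10 had an adjusted p of 0.0355 without yeast replicate 2 (at -0.49) (0.0355 to 0.809 over alternatives) and Il12a 0.0484 by limma-voom, 0.0405 scaled by library size alone and 0.0134 without yeast replicate 2 (0.0134 to 0.229).

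Several maturation genes rose, among them the costimulatory ligand Cd86 by 3.77 ± 0.15, Cd83 by 3.65 ± 0.09 and Ccr7, the receptor that guides dendritic cells to lymph nodes, by 2.36 ± 0.16. Nfkbiz rose by 2.66 ± 0.13, Egr1 by 2.62 ± 0.16 and Dusp10 by 4.75 ± 0.12. SRF and MRTF are transcription factors that respond to the pool of unpolymerised actin. Several of their targets rose, with Fhl2 at 5.47 ± 0.37, Cnn3 at 3.97 ± 0.13, the tropomyosin Tpm2 at 3.34 ± 0.12, beta-actin, Actb, at 1.63 ± 0.17 and Srf itself at 1.65 ± 0.28, and 17 of 26 rose, 2 fell (0 without 1 library of unstimulated, cytochalasin D or hyphae to 2 without yeast replicate 1) and 7 did not pass. 21 rose and 3 fell adjusted over the list alone (camera adjusted p = 6.3e-06, or 0.246 with an estimated correlation). Egln3 and Vegfa rose by 3.85 ± 0.12 and 3.03 ± 0.10, and in the ATF4 and unfolded-protein response Atf4 rose by 1.28 ± 0.09 and Asns, asparagine synthetase, by 1.60 ± 0.12. Among maturation genes, 13 of 18 rose, 3 fell (0 without cytochalasin D replicate 2 to 4 without 1 yeast library) and 2 did not pass. 14 rose and 4 fell adjusted over the list alone (camera adjusted p = 6.1e-05, or 0.157 if estimated). For NF-kB subunits and feedback targets, 12 of 18 rose, 2 fell (1 without 1 cytochalasin D library to 3 without 1 yeast library) and 4 did not pass. 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0014, or 0.271 if estimated). Of the AP-1, EGR and NR4A immediate-early genes, 16 of 22 rose, 3 fell and 3 did not pass, and the same over the list alone (camera adjusted p = 0.00015, or 0.271 if estimated). Of the MAP kinase phosphatases and SOCS genes, 10 of 16 rose, 2 fell (1 without cytochalasin D replicate 2 to 3 without 1 yeast library) and 4 did not pass. 10 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0014, or 0.246 if estimated). Among glycolysis genes and HIF-1 targets, 18 of 26 rose and 8 did not pass. 19 rose adjusted over the list alone (camera adjusted p = 9.3e-07, or 0.246 if estimated). For the ATF4 and unfolded-protein response, 10 of 21 rose, 2 fell (1 without 1 library of unstimulated, cytochalasin D or hyphae to 6 without yeast replicate 2) and 9 did not pass. 12 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.016, or 0.246 if estimated).

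Several receptor genes fell, with Clec4n at -2.66 ± 0.11, the mannose receptor Mrc1 at -2.36 ± 0.18, Clec4d, which encodes MCL, at -2.52 ± 0.21, Tlr2, a receptor for lipoproteins, at -2.47 ± 0.10 and Tlr4, the endotoxin receptor, at -4.12 ± 0.28, while Clec7a did not pass (-0.73 ± 0.26, adjusted p = 0.061). MHC class II genes present antigen to CD4 T cells, and of these H2-Aa stood at -1.04 ± 0.10 and their master regulator Ciita at -1.60 ± 0.17. Also lower were the sterol demethylase Cyp51 (-1.76 ± 0.15), the sterol transporter Abca1 (-1.77 ± 0.15), Gclm, a subunit of the enzyme that starts glutathione synthesis (-1.86 ± 0.09), and the proliferation marker Mki67 (-3.13 ± 0.21). Of the C-type lectin receptors and their signalling genes, 8 of 19 fell (5 without cytochalasin D replicate 2 to 13 without yeast replicate 1) and 11 did not pass. 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.019, or 0.246 with an estimated correlation). Of the Toll-like receptors and adaptors, 2 of 19 rose (1 without 1 cytochalasin D library to 6 without yeast replicate 1), 7 fell (7 without 1 library of unstimulated, cytochalasin D or hyphae to 12 without yeast replicate 2) and 10 did not pass, and the same over the list alone (camera adjusted p = 0.053). For MHC class II presentation, 6 of 10 fell and 4 did not pass. 7 fell adjusted over the list alone (camera adjusted p = 0.0085, or 0.431 if estimated). For cholesterol synthesis and uptake, 1 of 19 rose (1 without any of 7 libraries to 3 without yeast replicate 2), 9 fell (7 without 1 cytochalasin D library to 15 without yeast replicate 1) and 9 did not pass. 1 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.0085, or 0.246 if estimated). Of the sterol-efflux and LXR targets, 6 of 10 fell and 4 did not pass, and the same over the list alone (camera adjusted p = 0.028, or 0.246 if estimated). Among NRF2 antioxidant targets, 2 of 15 rose (0 without 1 library of unstimulated, cytochalasin D or hyphae to 3 without 1 yeast library), 8 fell (5 without 1 cytochalasin D library to 10 without yeast replicate 1) and 5 did not pass, and the same over the list alone (camera adjusted p = 0.016, or 0.246 if estimated). Among cell-cycle genes, 20 of 22 fell and 2 did not pass. 21 fell adjusted over the list alone (camera adjusted p = 6.9e-10, or 0.221 if estimated). C-type lectin receptor genes had an adjusted p of 0.0753 without yeast replicate 2 (9.21e-06 to 0.246 over alternatives), Toll-like receptor genes 0.0448 without yeast replicate 2 (median -0.37) and 0.0423 without cytochalasin D replicate 1 (0.00025 to 0.246) and MHC class II genes 0.0753 without yeast replicate 2 (0.000279 to 0.431). Sterol-efflux genes had an adjusted p of 0.398 without yeast replicate 2 (0.000492 to 0.398 over alternatives), NRF2 targets 0.0813 without yeast replicate 2 (0.000242 to 0.246) and Clec7a 0.0186 by DESeq2, 0.0318 scaled by library size alone, 0.021 without yeast replicate 1 (at -0.25) and 7.86e-08 without yeast replicate 2 (at -1.13) (7.86e-08 to 0.246).

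Markers of other cell types moved in the same comparison. The macrophage markers Mertk and Csf1r, the receptor for the macrophage growth factor, stood at -2.11 ± 0.10 and -2.37 ± 0.17. Eosinophil granule genes were among the largest falls, with Epx, eosinophil peroxidase, at -7.86 ± 0.54 and Prg2, major basic protein, at -6.15 ± 0.38 (-8.48 and -7.07 without cytochalasin D replicate 1). The monocyte marker Ccr2 stood at -2.61 ± 0.31 (-1.98 without yeast replicate 1) and the neutrophil marker S100a9 at -2.44 ± 0.34, whereas Lcn2, a siderophore binder that other activated cells also make, rose by 3.33 ± 0.18. Of conventional dendritic cell markers, Irf4 rose by 1.84 ± 0.10 and Clec9a fell by 4.56 ± 0.26. For macrophage markers, 5 of 11 fell (4 without 1 cytochalasin D library to 10 without yeast replicate 1) and 6 did not pass, and the same over the list alone (camera adjusted p = 0.0085, or 0.432 with an estimated correlation). Of the eosinophil markers, 5 of 7 fell and 2 did not pass, and the same over the list alone (camera adjusted p = 0.0085, or 0.246 if estimated). Among monocyte markers, 4 of 7 fell and 3 did not pass, and the same over the list alone (camera adjusted p = 0.019, or 0.247 if estimated). Among neutrophil markers, 1 of 9 rose, 7 fell and 1 did not pass, and the same over the list alone (camera adjusted p = 0.012, or 0.246 if estimated). For conventional dendritic cell markers, 5 of 11 rose, 4 fell and 2 did not pass. 5 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.66), with a median of 0.89 and a mean of -0.05. Among mitochondrially encoded genes, 0 of 13 fell (0 without 1 library of unstimulated, cytochalasin D or hyphae to 13 without yeast replicate 2) and 13 did not pass. 11 fell adjusted over the list alone (camera adjusted p = 0.028, or 0.634 if estimated). Macrophage markers had an adjusted p of 0.156 without yeast replicate 2 (median -0.29) (0.000308 to 0.432 over alternatives), monocyte markers 0.106 without yeast replicate 1 and 0.11 with the length and GC curve (0.00225 to 0.247) and neutrophil markers 0.0813 without yeast replicate 2 (0.0014 to 0.246). Mitochondrially encoded genes had an adjusted p of 0.204 without yeast replicate 1 (median -0.15), 0.0537 without cytochalasin D replicate 2 and 0.305 with the length and GC curve (median -0.21) (6.41e-05 to 0.634 over alternatives).

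Between yeast with cytochalasin D and yeast, 5320 genes differed, 2587 higher and 2733 lower, and 3004 by at least 2-fold. Camera called 21 of 41 lists, 10 higher and 11 lower, and 1 with an estimated correlation, while fry called 32. Library size alone gave 2091 higher and 3233 lower. The number of genes was 9821 without yeast replicate 2, 2840 and 2675 without cytochalasin D replicates 1 and 2, and 2541 in a fit of these groups alone.

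Called in the same direction in hyphae against yeast and in yeast with cytochalasin D against yeast were 1566 genes, 882 higher and 684 lower, where independent calls would give 382, and 73 genes were called in opposite directions. Both comparisons used the same yeast libraries. In 20 simulations of unchanged groups the number was 0.05 on average and at most 1, but simulated genes varied independently of each other, unlike genes in the yeast pair, and part of the excess can come from the shared controls. The covariance of the fold changes across genes, which are not independent replicates, was 0.675, of which the spread of the yeast pair accounted for 0.131. The number was 3415 without yeast replicate 1 and 7498 without yeast replicate 2. It was 683 and 686 without unstimulated replicates 1 and 2, 599 and 612 without cytochalasin D replicates 1 and 2, 302 and 284 without hyphae replicates 1 and 2, and 3640 with the length and GC curve subtracted. Genes called in opposite directions numbered 294 and 421 without yeast replicates 1 and 2, 25 and 25 without unstimulated replicates 1 and 2, 17 and 17 without cytochalasin D replicates 1 and 2, and 4 and 6 without hyphae replicates 1 and 2.

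**Figure D3:**
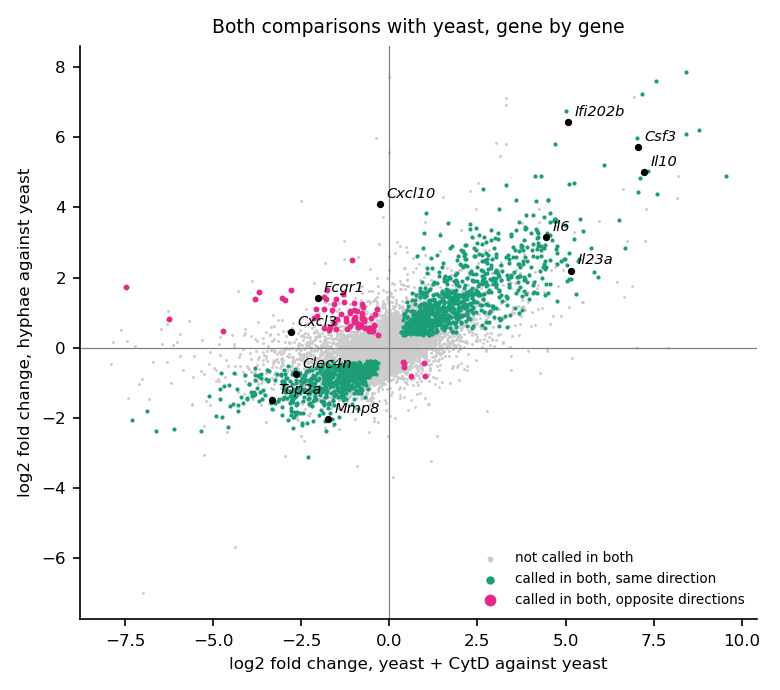
Log2 fold change against yeast for each of 13435 genes, with hyphae on one axis and yeast with cytochalasin D on the other. Green points are the 1566 genes called in the same direction in both, and pink points the 73 called in opposite directions.

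Hyphae were compared with yeast plus cytochalasin D, the 2 conditions in which size or the drug should limit uptake, to ask where the responses differed. Several interferon-inducible chemokines and interferon-stimulated genes were higher with hyphae: Cxcl10 by 4.34 ± 0.20, Cxcl11 by 3.89 ± 0.46 (4.53 without cytochalasin D replicate 1), Cmpk2 by 1.82 ± 0.11 and Oas2, a sensor of double-stranded RNA, by 1.91 ± 0.13. Several cytokines were lower with hyphae, with Il23a at -2.96 ± 0.15, Il12b at -1.82 ± 0.13, Il6 at -1.30 ± 0.21, Tnf at -1.50 ± 0.13 and Osm, oncostatin M, at -3.42 ± 0.19. The maturation genes Cd86, Cd83 and Ccr7 stood at -2.70 ± 0.15, -2 ± 0.09 and -1.37 ± 0.16, and the SRF-MRTF targets Fhl2 and Tpm2 at -4.15 ± 0.28 and -2.75 ± 0.12. Of the interferon-stimulated genes, 15 of 26 rose (8 without 1 library of cytochalasin D or hyphae to 21 without 1 yeast library) and 11 did not pass. 16 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.8e-06, or 0.195 with an estimated correlation). For Th1-promoting cytokines and chemokines, 4 of 10 rose, 1 fell (1 without 1 library of unstimulated, cytochalasin D or hyphae to 2 without 1 yeast library) and 5 did not pass. 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.04, or 0.286 if estimated). Of the Th17-promoting cytokines, 6 of 8 fell and 2 did not pass, and the same over the list alone (camera adjusted p = 1e-04, or 0.146 if estimated). Among other inflammatory and regulatory cytokines, 14 of 16 fell and 2 did not pass, and the same over the list alone (camera adjusted p = 2.8e-11, or 0.0624 if estimated). Among maturation genes, 1 of 18 rose (0 without 1 library of unstimulated, cytochalasin D or hyphae to 5 without 1 yeast library), 9 fell and 8 did not pass. 2 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.00048, or 0.146 if estimated). Of the actin cytoskeleton and SRF-MRTF targets, 2 of 26 rose (0 without 1 library of unstimulated, cytochalasin D or hyphae to 2 without 1 yeast library), 13 fell (6 without 1 library of cytochalasin D or hyphae to 22 without 1 yeast library) and 11 did not pass. 2 rose and 17 fell adjusted over the list alone (camera adjusted p = 9.8e-06, or 0.259 if estimated). Th1-promoting genes had an adjusted p of 0.129 without yeast replicate 1, 0.134 without yeast replicate 2, 0.0528 without cytochalasin D replicate 2 and 0.118 with the length and GC curve (0.00275 to 0.286 over alternatives) and Il6 0.0526 without cytochalasin D replicate 1, 0.054 without hyphae replicate 1 and 0.062 without hyphae replicate 2 (2.36e-12 to 0.062).

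Several receptors were higher with hyphae, with Clec4n at 1.90 ± 0.11, Clec4d at 2.32 ± 0.21, Tlr2 at 2.54 ± 0.10 and Tlr4 at 3.33 ± 0.28, while Clec7a did not pass (0.04 ± 0.26, adjusted p = 0.93). So were the MHC class II regulator Ciita (1.35 ± 0.17), Gclm (1.16 ± 0.09), Tbxas1, which makes thromboxane (2.02 ± 0.10), the inflammasome sensor Nlrp3 (1.82 ± 0.12) and adaptor Pycard (1.94 ± 0.16), Arg1 (3.58 ± 0.25) and Mki67 (2.36 ± 0.21). Of the C-type lectin receptors and their signalling genes, 9 of 19 rose (6 without cytochalasin D replicate 2 to 14 without 1 yeast library) and 10 did not pass. 10 rose adjusted over the list alone (camera adjusted p = 0.00059, or 0.146 with an estimated correlation). Of the Toll-like receptors and adaptors, 11 of 19 rose (6 without cytochalasin D replicate 2 to 15 without 1 yeast library) and 8 did not pass. 12 rose adjusted over the list alone (camera adjusted p = 3.5e-05, or 0.146 if estimated). For MHC class II presentation, 8 of 10 rose (4 without cytochalasin D replicate 1, cytochalasin D replicate 2 or hyphae replicate 1 to 10 without 1 yeast library) and 2 did not pass, and the same over the list alone (camera adjusted p = 1e-04, or 0.283 if estimated). Among NRF2 antioxidant targets, 7 of 15 rose (4 without 1 library of cytochalasin D or hyphae to 12 without 1 yeast library) and 8 did not pass. 9 rose adjusted over the list alone (camera adjusted p = 0.00048, or 0.146 if estimated). For eicosanoid synthesis and receptors, 6 of 13 rose, 2 fell (0 without 1 library of cytochalasin D or hyphae to 3 without 1 yeast library) and 5 did not pass, and the same over the list alone (camera adjusted p = 0.023, or 0.195 if estimated). For the inflammasome and pyroptosis, 7 of 12 rose (4 without cytochalasin D replicate 2 to 9 without 1 yeast library), 1 fell (0 without 1 library of cytochalasin D or hyphae to 2 without 1 yeast library) and 4 did not pass, and the same over the list alone (camera adjusted p = 0.002, or 0.146 if estimated). In nitric oxide, arginine and itaconate metabolism, 4 of 9 rose, 1 fell (0 without 1 library of cytochalasin D or hyphae to 1 without 1 library of unstimulated or yeast) and 4 did not pass, and the same over the list alone (camera adjusted p = 0.02, or 0.195 if estimated). Among cell-cycle genes, 15 of 22 rose (9 without cytochalasin D replicate 1, cytochalasin D replicate 2 or hyphae replicate 1 to 18 without 1 yeast library) and 7 did not pass. 16 rose adjusted over the list alone (camera adjusted p = 8e-07, or 0.195 if estimated).

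Several markers of other cell types were higher with hyphae too, with the macrophage Fc receptor Fcgr1 at 3.44 ± 0.16, the monocyte marker Ly6c2 at 2.92 ± 0.18, the neutrophil granule gene Ngp at 3.96 ± 0.30 and the eosinophil granule genes Epx and Prg2 at 8.02 ± 0.54 and 6.22 ± 0.38 (8.65 and 7.14 without cytochalasin D replicate 1). For macrophage markers, 8 of 11 rose (5 without 1 library of cytochalasin D or hyphae to 10 without 1 yeast library) and 3 did not pass. 10 rose adjusted over the list alone (camera adjusted p = 1.4e-05, or 0.281 with an estimated correlation). Among monocyte markers, 5 of 7 rose (3 without cytochalasin D replicate 2 to 6 without 1 yeast library) and 2 did not pass, and the same over the list alone (camera adjusted p = 0.0013, or 0.195 if estimated). Among neutrophil markers, 5 of 9 rose (2 without cytochalasin D replicate 2 to 7 without 1 yeast library), 1 fell (1 without 1 library of unstimulated, cytochalasin D or hyphae to 2 without 1 yeast library) and 3 did not pass. 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.024, or 0.24 if estimated). Of the eosinophil markers, 4 of 7 rose and 3 did not pass. 5 rose adjusted over the list alone (camera adjusted p = 0.0058, or 0.195 if estimated). Neutrophil markers had an adjusted p of 0.0796 without yeast replicate 1 and 0.0813 without yeast replicate 2 (0.00148 to 0.24 over alternatives).

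Between hyphae and yeast with cytochalasin D, 2952 genes differed, 1711 higher and 1241 lower with hyphae, and 1650 by at least 2-fold. Camera called 23 of 41 lists, 16 higher and 7 lower, and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05 and fry called 31. Library size alone gave 1867 higher and 1014 lower, and the length and GC curve 2710 higher and 3679 lower. The number of genes was 7410 and 7402 without yeast replicates 1 and 2, 1263 and 1191 without cytochalasin D replicates 1 and 2, 1276 (869 higher, 407 lower) and 1443 without hyphae replicates 1 and 2, and 8217 in a fit of these groups alone.

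Yeast was compared with unstimulated cells to give the response to the smaller form of the fungus. Il1b rose by 5.09 ± 0.10, Il12b by 6.90 ± 0.22 and Il6 by 2.74 ± 0.31, and Il12a, with 0 counts in both unstimulated libraries, was at least 40.1-fold higher (floor of 3 counts over the group). The neutrophil chemokines Cxcl3 and Cxcl2 rose by 5.11 ± 0.15 and 3.53 ± 0.10, the interferon-stimulated gene Ifit1 by 3.26 ± 0.14, the peroxiredoxin Prdx1 by 2.71 ± 0.13, and Cd83 and Cd86 by 1.99 ± 0.10 and 1.97 ± 0.15. Clec4e, which encodes the lectin Mincle, rose by 4.79 ± 0.20 and Clec7a by 1.85 ± 0.26, whereas Mrc1 stood at -2.48 ± 0.17, the squalene synthase Fdft1 at -1.23 ± 0.13 and the cell-division gene Birc5 at -2.59 ± 0.14. Of the Th17-promoting cytokines, 6 of 8 rose and 2 did not pass, and the same over the list alone (camera adjusted p = 7.8e-06, or 0.0626 with an estimated correlation). Of the neutrophil-attracting CXC chemokines, 6 of 6 rose, and the same over the list alone (camera adjusted p = 4.6e-06, or 0.0907 if estimated). Of the interferon-stimulated genes, 26 of 26 rose, and the same over the list alone (camera adjusted p = 2.5e-15, or 0.0816 if estimated). Among maturation genes, 13 of 18 rose, 1 fell and 4 did not pass. 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.3e-07, or 0.0626 if estimated). Among NRF2 antioxidant targets, 11 of 15 rose and 4 did not pass. 12 rose adjusted over the list alone (camera adjusted p = 1.6e-07, or 0.0626 if estimated). Of the C-type lectin receptors and their signalling genes, 6 of 19 rose, 7 fell (2 without unstimulated replicate 1 to 10 without yeast replicate 2) and 6 did not pass. 7 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.74). For cholesterol synthesis and uptake, 12 of 19 fell (6 without unstimulated replicate 1 to 18 without yeast replicate 1) and 7 did not pass. 16 fell adjusted over the list alone (camera adjusted p = 7.8e-06, or 0.0626 if estimated). Among cell-cycle genes, 20 of 22 fell and 2 did not pass, and the same over the list alone (camera adjusted p = 1.2e-12, or 0.0838 if estimated). Of the mast cell and basophil markers, 1 of 3 rose (1 without any of 7 libraries to 2 without yeast replicate 1) and 2 did not pass, and the same over the list alone (camera adjusted p = 0.042, or 0.294 if estimated). Among mitochondrially encoded genes, 0 of 13 rose (0 without 1 library of unstimulated, cytochalasin D or hyphae to 13 without yeast replicate 2) and 13 did not pass, and the same over the list alone (camera adjusted p = 0.04, or 0.735 if estimated), with a median of 0.86 (1.42 without yeast replicate 2). Among ribosomal protein genes, a sign of RNA quality, 12 of 21 fell (1 without unstimulated replicate 1 to 21 without yeast replicate 1) and 9 did not pass. 15 fell adjusted over the list alone (camera adjusted p = 4.9e-05, or 0.366 if estimated). Mast cell markers had an adjusted p of 0.0922 without yeast replicate 1, 0.222 without yeast replicate 2 and 0.102 with the length and GC curve (0.00204 to 0.294 over alternatives) and mitochondrially encoded genes 0.114 without unstimulated replicate 1, 0.839 without yeast replicate 1 (median 0.02) and 0.144 with the length and GC curve (median 0.23) (5.14e-05 to 0.839).

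Yeast with cytochalasin D was also set against unstimulated cells. Il12b rose by 10.22 ± 0.22, Il6 by 7.19 ± 0.30, Tnf by 6.48 ± 0.13 and the chemokine Ccl5 by 8.06 ± 0.18. Csf2, with 0 counts in unstimulated cells, was at least 717-fold higher, and Il23a, with 3, was 485-fold higher (counting interval 166 to 2360). Cd86, Cd83, Ifit1, Egln3 and Cnn3 rose by 5.74 ± 0.15, 5.63 ± 0.10, 5.12 ± 0.14, 6.75 ± 0.13 and 5.55 ± 0.13. Clec4e rose by 3.73 ± 0.20 and Clec7a by 1.12 ± 0.26, whereas Mrc1 stood at -4.85 ± 0.18, Tlr4 at -3.90 ± 0.28, Tbxas1 at -3.67 ± 0.10, the lipoxygenase Alox5 at -3.76 ± 0.16, Csf1r at -2.81 ± 0.17 and Birc5 at -5.16 ± 0.16. Among other inflammatory and regulatory cytokines, 16 of 16 rose, and the same over the list alone (camera adjusted p = 1.8e-11, or 0.0635 with an estimated correlation), with a median of 5.89, or 5.5 with genes near the floor at their bound. Of the Th17-promoting cytokines, 8 of 8 rose, and the same over the list alone (camera adjusted p = 3.8e-06, or 0.0709 if estimated). Of the interferon-stimulated genes, 25 of 26 rose and 1 did not pass. 25 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.7e-11, or 0.133 if estimated). Among maturation genes, 15 of 18 rose, 2 fell (1 without 1 library of unstimulated or cytochalasin D to 2 without 1 library of yeast or hyphae) and 1 did not pass, and the same over the list alone (camera adjusted p = 2.3e-06, or 0.0709 if estimated). Among glycolysis genes and HIF-1 targets, 22 of 26 rose and 4 did not pass, and the same over the list alone (camera adjusted p = 1.3e-06, or 0.257 if estimated). Of the actin cytoskeleton and SRF-MRTF targets, 17 of 26 rose, 3 fell (1 without cytochalasin D replicate 2 to 4 without 1 yeast library) and 6 did not pass. 18 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.001, or 0.298 if estimated). Of the C-type lectin receptors and their signalling genes, 6 of 19 rose (3 without unstimulated replicate 2 or cytochalasin D replicate 1 to 6 without 1 yeast library), 12 fell and 1 did not pass, and the same over the list alone (camera adjusted p = 0.14). For eicosanoid synthesis and receptors, 2 of 13 rose, 9 fell and 2 did not pass, and the same over the list alone (camera adjusted p = 0.028, or 0.229 if estimated). For macrophage markers, 1 of 11 rose and 10 fell, and the same over the list alone (camera adjusted p = 0.00032, or 0.298 if estimated). Among monocyte markers, 1 of 7 rose and 6 fell, and the same over the list alone (camera adjusted p = 0.027, or 0.275 if estimated). Of the eosinophil markers, 1 of 7 rose (0 without any of 5 libraries to 1 without unstimulated replicate 2, yeast replicate 1 or yeast replicate 2), 5 fell and 1 did not pass. 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.036, or 0.275 if estimated). Among cell-cycle genes, 22 of 22 fell, and the same over the list alone (camera adjusted p = 4e-12, or 0.121 if estimated). Among ribosomal protein genes, a sign of RNA quality, 17 of 21 fell (6 without cytochalasin D replicate 2 to 21 without 1 yeast library) and 4 did not pass, and the same over the list alone (camera adjusted p = 0.00037, or 0.298 if estimated). Monocyte markers had an adjusted p of 0.0623 scaled by library size alone (0.000257 to 0.275 over alternatives), eosinophil markers 0.0785 scaled by library size alone, 0.0614 without unstimulated replicate 2, 0.0728 without yeast replicate 1, 0.0749 without yeast replicate 2 and 0.0832 with the length and GC curve (6.85e-05 to 0.275) and Clec7a 0.073 without unstimulated replicate 1, 0.0518 without unstimulated replicate 2 and 0.0551 without cytochalasin D replicate 1 (4.07e-09 to 0.073).

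Hyphae were set against unstimulated cells in the same way. Il12b rose by 8.39 ± 0.22, Il6 by 5.90 ± 0.30, Tnf by 4.98 ± 0.13 and Cxcl10 by 4.99 ± 0.20. Il23a was 62.2-fold higher (counting interval 21 to 305), Csf2 at least 117-fold and Ifnb1, which encodes interferon beta, 23.5-fold (counting interval 6.13 to 200). Rsad2, Ifit1, Tnfaip3, Nos2, Egln3 and Irg1, which makes itaconate, rose by 5.70 ± 0.14, 5.33 ± 0.14, 3.48 ± 0.10, 8.71 ± 0.21, 6.30 ± 0.13 and 6.26 ± 0.10. Clec4e rose by 5.14 ± 0.20 and Clec7a by 1.16 ± 0.26, whereas Mrc1 stood at -3.05 ± 0.17, Fdft1 at -1.60 ± 0.13 and Birc5 at -3.78 ± 0.14. Of the Th17-promoting cytokines, 8 of 8 rose, and the same over the list alone (camera adjusted p = 7.2e-07, or 0.0579 with an estimated correlation). For Th1-promoting cytokines and chemokines, 9 of 10 rose and 1 fell (0 without 1 library of unstimulated or hyphae to 1 without 1 library of yeast or cytochalasin D), and the same over the list alone (camera adjusted p = 6e-06, or 0.0767 if estimated). Of the interferon-stimulated genes, 26 of 26 rose, and the same over the list alone (camera adjusted p = 8e-18, or 0.0626 if estimated). For NF-kB subunits and feedback targets, 18 of 18 rose, and the same over the list alone (camera adjusted p = 1.2e-08, or 0.118 if estimated). Among glycolysis genes and HIF-1 targets, 21 of 26 rose and 5 did not pass, and the same over the list alone (camera adjusted p = 1.1e-08, or 0.179 if estimated). In nitric oxide, arginine and itaconate metabolism, 7 of 9 rose and 2 did not pass. 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 1e-04, or 0.0626 if estimated). Of the C-type lectin receptors and their signalling genes, 8 of 19 rose (4 without unstimulated replicate 2 or hyphae replicate 1 to 9 without 1 yeast library), 5 fell (2 without unstimulated replicate 1, hyphae replicate 1 or hyphae replicate 2 to 10 without 1 yeast library) and 6 did not pass. 9 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.78), with a median of -0.24, a mean of 0.06 and a test direction of up. Of the actin cytoskeleton and SRF-MRTF targets, 7 of 26 rose (4 without unstimulated replicate 1, hyphae replicate 1 or hyphae replicate 2 to 13 without 1 yeast library), 1 fell (0 without 1 library of unstimulated, cytochalasin D or hyphae to 5 without 1 yeast library) and 18 did not pass. 5 rose adjusted over the list alone (camera adjusted p = 0.26). For cholesterol synthesis and uptake, 16 of 19 fell and 3 did not pass. 17 fell adjusted over the list alone (camera adjusted p = 7.2e-07, or 0.0579 if estimated). Among cell-cycle genes, 22 of 22 fell, and the same over the list alone (camera adjusted p = 4.2e-14, or 0.0626 if estimated). Among ribosomal protein genes, a sign of RNA quality, 12 of 21 fell (7 without hyphae replicate 2 to 21 without 1 yeast library) and 9 did not pass. 14 fell adjusted over the list alone (camera adjusted p = 1e-04, or 0.338 if estimated). Clec7a had an adjusted p of 0.0854 without unstimulated replicate 1, 0.0626 without unstimulated replicate 2 and 0.0645 without hyphae replicate 1 (1.13e-10 to 0.0854 over alternatives).

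Against unstimulated cells, 4333 genes differed with yeast (2207 higher, 2126 lower), 7162 with yeast and cytochalasin D (3563 higher, 3599 lower) and 5502 with hyphae (2832 higher, 2670 lower), and 2257, 4481 and 3253 of these changed by at least 2-fold. Camera called 18, 23 and 20 of 41 lists, and 0 in each with an estimated correlation, where 12, 9 and 15 had an unadjusted p under 0.05 and fry called 30, 35 and 31. Scaled by library size alone, the median of all genes was -0.244, -0.327 and -0.26, and the changed genes split 1368 to 3287, 2429 to 5116 and 2048 to 4129, higher to lower. With yeast the number was 1760 and 1966 without unstimulated replicates 1 and 2, 6818 and 9636 without yeast replicates 1 and 2, 1444 in a fit of these groups alone and 6679 with the length and GC curve subtracted. With hyphae it was 3462 and 3442 without unstimulated replicates 1 and 2, 9488 and 9497 without yeast replicates 1 and 2, 3383 and 3286 without hyphae replicates 1 and 2, 9127 in a fit of these groups alone and 8372 with the curve.

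Changed in the same direction by all 3 stimuli were 2926 genes, 1374 higher and 1552 lower, of 8388 called for any of them. This number was 1413 and 1539 without unstimulated replicates 1 and 2, 5345 and 4857 without yeast replicates 1 and 2, 1942 and 1940 without hyphae replicates 1 and 2, and 4876 with the length and GC curve subtracted. Pairwise, 4638 genes were shared by hyphae and yeast with cytochalasin D, where independent calls would give 1466, 3317 by yeast and hyphae (888) and 3333 by yeast and yeast with cytochalasin D (1155). The unstimulated libraries were common to all 3 comparisons and, since each part would hold 1 library, were not divided between them, so part of this excess may come from shared controls. In 20 simulations of unchanged groups at most 1 gene was shared in each pair, and the spread of the unstimulated pair accounted for 0.0234 of covariances of 2.06, 1.16 and 1.32. In the same order the numbers were 2953, 1585 and 1491 without unstimulated replicate 1, 2921, 1732 and 1653 without unstimulated replicate 2, 7829, 6048 and 5622 without yeast replicate 1, and 7833, 5555 and 5809 without yeast replicate 2. The first 2 were 3003 and 2137 without hyphae replicate 1 and 2911 and 2135 without hyphae replicate 2, and the last was 2216 without cytochalasin D replicate 1.

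**Figure D4:**
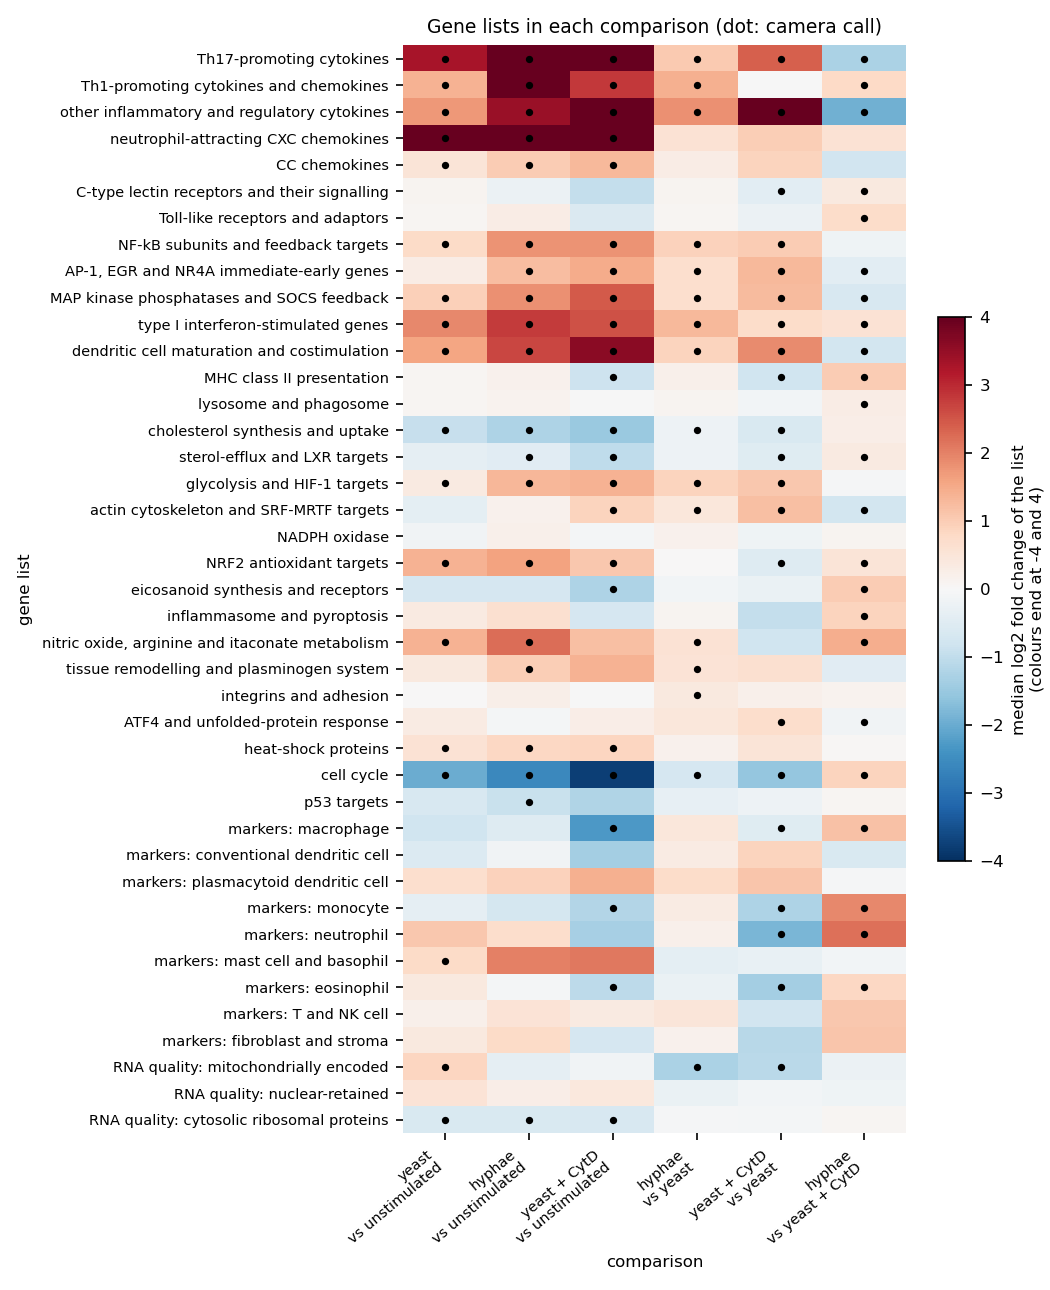
Median log2 fold change of each gene list (colour, which ends at -4 and 4) in the 6 comparisons, with a dot where camera with its preset correlation called the list. Cell-cycle genes had medians of -2, -3.78 and -2.57 in yeast, yeast with cytochalasin D and hyphae against unstimulated cells.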

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

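The tests of eosinophil-lineage cells and of the part of yeast replicate 1 in the difference between hyphae and yeast, and the alternatives that subtract a curve in length and GC content, thin the libraries or leave out mitochondrially encoded genes, were chosen after the results they concern had been seen.

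Genes called in opposite directions against unstimulated cells by different stimuli showed where the stimuli parted, and in each the direct difference between the stimuli was called as well. Yeast and hyphae had 26 such genes, 6 of them higher with yeast, among them Tnfsf14, a cytokine of the TNF family (-1.17 with yeast, 1.82 with hyphae, direct difference 2.99), and the collagenase Mmp8 (1.08, -0.95 and -2.02). Hyphae and yeast with cytochalasin D had 126, 101 of them higher with hyphae, among them the formyl peptide receptor Fpr2 (0.74 with hyphae, -4.21 with the drug, direct difference 4.95) and the smooth-muscle actin Actg2 (-1.16, 3.41 and -4.56). Yeast and yeast with cytochalasin D had 196, 125 of them higher with yeast, among them Osbpl3, a lipid-binding protein (1.45 with yeast, -1.73 with the drug, direct difference -3.18). The 3 numbers, in this order, moved with every library: they were 115, 461 and 524 without yeast replicate 1 and 1581, 463 and 1845 without yeast replicate 2. They were 7, 47 and 47 without unstimulated replicate 1, 4, 52 and 53 without unstimulated replicate 2, 13, 67 and 100 without cytochalasin D replicate 1, and 13, 68 and 100 without cytochalasin D replicate 2. Without hyphae replicate 1 they were 8, 61 and 117, and without hyphae replicate 2 they were 7, 66 and 118. Tnfsf14 in yeast against unstimulated cells had an adjusted p of 0.0558 with these groups alone (0.00103 to 0.0558 over alternatives).

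Spike-in controls, which no comparison used, had 62 counts in hyphae replicate 1 and 1 in hyphae replicate 2, against 0 in the other libraries.

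The yeast libraries differed more than any other pair, with an SD of 0.581 over genes above 32 CPM, and 6.52% of these genes differed by over 2-fold. Across 6791 genes the difference had a correlation of -0.0917 with the effect of yeast. This argues against weaker or no stimulation of yeast replicate 1 as the main cause, and leaves a smaller part open. The SD of 0.579 without 13 mitochondrial genes argues against those alone. Recovery that depended on the GC content or length of transcripts is a candidate explanation, because a smooth curve in both explained 74.5% of the variance of the difference (GC content alone 74.2%, length alone 5.96%), against 62.6%, 32.9% and 31.7% in the unstimulated, cytochalasin D and hyphae pairs. A line in GC content fitted on 4741 nuclear genes predicted 69.1% of the difference in mitochondrially encoded genes (0.98 of 1.42), whose high share in yeast replicate 1 may thus be part of the same trend. What produced the trend, in handling, library making or sequencing, was not measured, and apart from weaker stimulation no biological explanation was tested.

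The difference between hyphae and yeast was weighed against the same library; a first test, the share of the 1940 called genes still called without yeast replicate 1 (98.1%), was replaced, since genes called already had both yeast libraries on one side. In 758 genes above 32 CPM chosen by a difference of at least 2-fold between hyphae replicate 1 and yeast replicate 1, the median difference in that direction between hyphae replicate 2 and yeast replicate 2 was 36.2% as large (0.454 of 1.25, and 28.6% with the hyphae libraries exchanged), between the bounds set for this test, so how much of the difference came from yeast replicate 1 stays undecided, although 96.2% of these genes kept the direction. Of the called genes, 94.3% kept call and direction with the length and GC curve subtracted, 91.2% with libraries thinned, and 0 reversed. The median called gene kept 85.1% of its log2 fold change with the curve. These genes too had both yeast libraries on one side. For them only this argues against recovery by length and GC content and against library size, each as sole cause. Length and GC content explained 18.2% of the variance of the fold changes. The number of genes moved widely with the library left out, which changes the spread in the fit and the fold changes together, so it is no measure of how many genes differ. A response to the form of the fungus stays open as a hypothesis, beside the part that yeast replicate 1 had in the difference.

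Transcripts of eosinophil markers were low in yeast with cytochalasin D against yeast, with Epx at -7.86 ± 0.54, Prg2 at -6.15 ± 0.38 (-8.48 and -7.07 without cytochalasin D replicate 1), Ear1 at -4.41 ± 0.19, Ear6 at -1.37 ± 0.12 and Siglecf at -0.66 ± 0.13; Ear1 and Ear6 are paralogs that can share reads, and Siglecf was named after its values were seen. Library size was argued against, since 5 of the 5 markers called were still called with libraries thinned. The smallest fall, 0.66, was below 0.5 times the median fall of 4.41 by more than 2 standard errors. This argues against fewer eosinophil-lineage cells as whole cause only if no other cells make the markers. A count of small falls, tried after this test had been seen, left it undecided. Fewer such cells, with other cells making Siglecf or Ear6, and a change in transcription stay open. Siglecf had an adjusted p of 0.0718 with these groups alone, 0.0675 without cytochalasin D replicate 1 and 0.0595 without cytochalasin D replicate 2 (5.18e-07 to 0.0718 over alternatives).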

How the results depend on the processing

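The length and GC curve, thinning and leaving out mitochondrial genes were chosen after the data were seen. Of 175 called results of single genes named here, checked under 20 alternatives, 3463 of 3487 checks kept direction and call, 24 lost the call and 0 reversed. Gene counts stayed within 1.5 times in 82 checks, were larger in 16 and smaller in 22. Genes changed by 1.5-fold were recovered in 4% of simulated cases, which limits what these libraries can show.

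With 1 library left out, the number of changed genes ran from 324 to 9262 for hyphae against yeast, 2675 to 9821 for yeast with cytochalasin D against yeast, 1191 to 7410 for hyphae against yeast with cytochalasin D, and 1760 to 9636, 4932 to 10484 and 3286 to 9497 for yeast, yeast with cytochalasin D and hyphae against unstimulated cells. The highest number of genes in each of these came without a yeast library; with 1 library in the group its spread no longer enters the fit. The numbers of lists called ran from 15 to 22, 16 to 24, 21 to 23, 15 to 18, 20 to 24 and 18 to 21 in the same order. Genes shared by hyphae and yeast with cytochalasin D against yeast ran from 284 to 7498, and genes shared by the 3 stimuli from 1413 to 5345, both highest without a yeast library.

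DESeq2 called 3110 genes for hyphae against yeast, and the cause was not tested. Fits of the groups compared alone gave fewer genes in yeast comparisons (hyphae 171, with drug 2541, unstimulated 1444). Hyphae gave more against the drug (8217) and unstimulated cells (9127). The main fit pools spread, so tighter pairs lower errors for yeast. The length and GC curve gave 5029 for hyphae against yeast, 6389 for hyphae against yeast with cytochalasin D, 6679 for yeast and 8372 for hyphae against unstimulated cells, with 3640 and 4876 shared genes, and the curve lowered the SD of the yeast pair from 0.581 to 0.295. With it, 40.2% of the genes changed between hyphae and yeast were higher with hyphae, against 59.1% before, and the cause was not tested. A replicate block gave 1237 genes for hyphae against yeast and 1026 shared genes. Deviations of equally numbered libraries correlated at -0.336 to 0.115 across genes. GC trends enter these, so pairing stays undecided.

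With an estimated correlation camera called 1 list in all, and 6 to 15 lists per comparison had an unadjusted p under 0.05. Fry called 26, 32, 30, 35 and 31 lists in hyphae and yeast with cytochalasin D against yeast and in yeast, yeast with cytochalasin D and hyphae against unstimulated cells. Fry also gave the opposite direction to camera, which had made no call, for conventional dendritic cell markers in hyphae against yeast with cytochalasin D (median -0.60, fry adjusted p = 0.00857) and in yeast with cytochalasin D against unstimulated cells (median -1.36, 0.0109), and for inflammasome genes in the latter (median -0.67, 0.00115); fry does not compare a list with other genes, and the cause was not tested. Of 121 called results of lists, checked under 11 alternatives with the preset correlation, 1275 of 1331 checks kept direction and call, 56 lost the call and 0 reversed, and results without a call gained one in 44 of 1375 checks. Fry lost 3 of the 121 calls, and an estimated correlation lost 120.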

Other observations

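The tests of a graded response and of SRF-MRTF targets are hypotheses of a re-analysis; the SRF-MRTF test was chosen after its result had been seen.

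Beyond the lists described for yeast with cytochalasin D against yeast, the largest rises included Slc13a5, a citrate transporter, at 9.55 ± 0.61 and the chemokine receptor Cxcr3 at 8.43 ± 0.76 (12.71 without yeast replicate 2). The largest falls included Tgfbi, an adhesion protein induced by TGF-beta, at -5.31 ± 0.14 and Fpr2 at -5.08 ± 0.11. Of the tissue remodelling and plasminogen genes, 9 of 17 rose, 4 fell (4 without any of 7 libraries to 7 without yeast replicate 2) and 4 did not pass, and the same over the list alone (camera adjusted p = 0.078). In the same list with hyphae against yeast, 7 of 17 rose (4 without 1 hyphae library to 12 without yeast replicate 2), 2 fell (1 without 1 library of unstimulated, cytochalasin D or hyphae to 4 without yeast replicate 1) and 8 did not pass. 10 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0091, or 0.144 with an estimated correlation). Serpinb2, an inhibitor of plasminogen activators, rose by 3.1 ± 0.26 there. For integrins and adhesion with hyphae against yeast, 3 of 15 rose (1 without hyphae replicate 2 to 9 without 1 yeast library) and 12 did not pass. 4 rose adjusted over the list alone (camera adjusted p = 0.0091, or 0.144 if estimated), with Itgb3 at 2.78 ± 0.17. Remodelling genes in yeast with cytochalasin D against yeast had an adjusted p of 0.0331 without yeast replicate 1 and 0.0354 with the length and GC curve (1.61e-05 to 0.246 over alternatives) and integrin genes in hyphae against yeast 0.0869 without yeast replicate 2 (median 0.60) (4.52e-05 to 0.144).

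Against unstimulated cells, several heat-shock genes rose, with the chaperone Hsph1 at 1.28 ± 0.14 with yeast, 1.80 ± 0.14 with yeast and cytochalasin D and 1.35 ± 0.14 with hyphae. Of the heat-shock genes with yeast, 6 of 12 rose (2 without 1 unstimulated library to 11 without yeast replicate 1) and 6 did not pass. 8 rose adjusted over the list alone (camera adjusted p = 0.0013, or 0.0907 with an estimated correlation). With the drug, 10 of 12 rose (6 without unstimulated replicate 2 to 10 without 1 yeast library) and 2 did not pass, and the same over the list alone (camera adjusted p = 0.0027, or 0.133 if estimated). With hyphae, 10 of 12 rose (5 without 1 unstimulated library to 10 without 1 yeast library) and 2 did not pass, and the same over the list alone (camera adjusted p = 0.001, or 0.0767 if estimated).

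The order of groups along the first principal component raised the hypothesis of 1 graded response. Of 7162 genes called for yeast with cytochalasin D against unstimulated cells, 44.7% (3200) had ordered group means, below the bound set beforehand. The order was unstimulated, yeast, hyphae, yeast with cytochalasin D or its reverse. With hyphae, 72% moved beyond yeast and 1182 beyond yeast with cytochalasin D. Noise, not modelled, may break this order, so 44.7% decides nothing. The 126 genes called in opposite directions with hyphae argue against 1 graded response of all, and a graded part stays open.

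Raised SRF-MRTF targets with cytochalasin D could come from an absence of uptake, if hyphae share it, or from the drug, which acts on actin; uptake was not measured. The median log2 difference of the list for hyphae against yeast with cytochalasin D was -0.75 (camera adjusted p = 9.8e-06, adjusted p = 0.259 with an estimated correlation), which argues against an absence of uptake shared equally with hyphae as the whole cause, and leaves open an unequal one. An effect of the drug on actin apart from uptake stays open, since no library held the drug alone.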
